A study of Arabidopsis thaliana with 12 samples.

How the data were processed

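RNA of rosette leaves from 12 Arabidopsis thaliana plants was measured, with a single array per plant. All plants were of the Columbia ecotype and carried rmpA and rmpB, bacterial genes whose chloroplast-targeted products bind formaldehyde to a pentose phosphate and turn the product into fructose phosphate. Plants without these genes were not analysed here. Per the labels, 7-week-old plants were acclimated for 72 h in constant light at 24 °C and then treated for 150 min in the light. The 4 groups held 3 plants each: outside (not placed in the exposure chamber, under 0.08 ppm formaldehyde), air (in the ventilated 10 L chamber, under 0.04 ppm), low (in the chamber, 1 to 2 ppm) and high (in the chamber, 14 to 16 ppm). The 3 plants of a chamber condition shared a chamber run, so run and condition cannot be told apart. No p-value below covers the spread between runs, and those for single genes measure the spread between plants of a group. About 100 mg of leaf and 10 µg of total RNA went into each biotin-labelled target.

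The deposited values are log2 intensities that the authors made with GCRMA, a method that corrects background from probe sequence and summarises probes to a probe set. Its version and options are not given in the sources used here, and the array scans were not used here. The values were used as deposited. The table held 22810 probe sets, of which 64 were array controls, and the other 22746 were tested without a filter on signal. Medians of the 12 arrays ran from 5.68 to 5.82. The lowest value, 2.11, was shared by 26.6% to 28.0% of the probe sets of an array, and 3999 probe sets sat at it on all arrays. Depth has no meaning for these arrays, and the 3 plants per group limit the precision.

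Probe sets were tied to genes by the supplied annotation table. It paired 13513 tested probe sets with 1 gene, 503 with several and 8730 with none, and 13436 of the 1-gene probe sets were found in the reference gene table (assembly TAIR10.1, used for names only). Of the 1-gene probe sets, 1628 had a symbol and 11885 only a locus. The array's genome positions were not used here.

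Group means were compared in R 4.3.3 with limma 3.58.1: a linear model on all 12 arrays with 8 residual degrees of freedom, moderated variances with a mean trend, two-sided tests and Benjamini-Hochberg adjustment over the 22746 probe sets. A probe set was called at an adjusted p under 0.05. An adjusted p in the text is from limma unless another test is named. The comparisons were high against air, low against air, high against low and air against outside. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The limma steps were tested on simulated data for 22746 probe sets, with the spread within groups of all 12 arrays. In high against air, 50 of 100 probe sets changed by log2 1 and 90 of 100 changed by log2 2 were called. With them 11 unchanged ones were called, so that 7.28% of the calls were false. Far fewer probe sets were changed than the 7867 called in the real comparison, so these rates do not carry over to it.

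Before the data were examined, the groups, comparisons, tests, threshold, gene lists, rule for named genes and most alternatives were fixed. Genes were named by rank: per direction, up to 12 genes (6 for high against low) with an adjusted p under 0.05, a log2 change of at least 1 and no overlap between the plants of both groups, of which up to 3 were known only by locus. Formate dehydrogenase was always named, as were up to 4 members of each list with the smallest adjusted p. In comparisons other than high against air, list members were named where they passed the threshold. The rule also asked for ADH2/HOT5, SFGH and THFS, enzymes of formaldehyde and formate metabolism, but no probe set was paired with them. Of the 405 members of 25 lists, 58 had a probe set. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 3 lists tested. Camera compares the members with all other probe sets, so its p-value rests on the spread among probe sets. The correlations estimated from the data were 0.0939 for heat shock, 0.435 for detoxification and 0.159 for reactive oxygen. Lists with fewer members are given as values, and the lists for jasmonate, DNA damage, inflorescence, epidermis, phloem and xylem had 0 measured members. A fold against a group lying within 0.5 of the lowest value is given as a lower bound.

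RNA quality was read from the 3' minus 5' signal of control probe sets, with exact permutation tests over 15400 partitions of the arrays, adjusted over 4 measures. The overlap of the low and high responses was compared with 200 simulations of unchanged groups sharing the air arrays. Alternatives were other normalizations, filters on dim probe sets, variance models, thresholds, control groups, array weights, a replicate block, set tests and each array left out in turn. Leaving out air plants 2 and 3, and leaving out probe sets near the lowest value, were added after the values were seen.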

Results

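Leaf transcript levels were measured in formaldehyde-assimilating transgenic Arabidopsis, in 3 plants each kept outside the chamber, in chamber air, at 1 to 2 ppm (low) and at 14 to 16 ppm formaldehyde (high). On the first principal component, with 67.7% of the variance, the high plants lay between 119.7 and 136.1 and the other plants between -60.6 and -25.3. The second component (12.2%) parted air plants 2 and 3, at 49.6 and 69.5, from air plant 1 at -9.01 and from the low plants at -44.8 to -29.0. Air plant 1 correlated most closely with low plant 1 (r = 0.995 across probe sets, which are not independent replicates). The 3' minus 5' signal, a sign of RNA quality, differed between the groups for GAPDH (exact permutation p = 0.00727, adjusted 0.0145) and ubiquitin (exact permutation p = 0.00351, adjusted 0.0140). It did not pass for actin (exact permutation p = 0.156), and the mean hybridization control did not either (exact permutation p = 0.142).

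**Figure D1:**
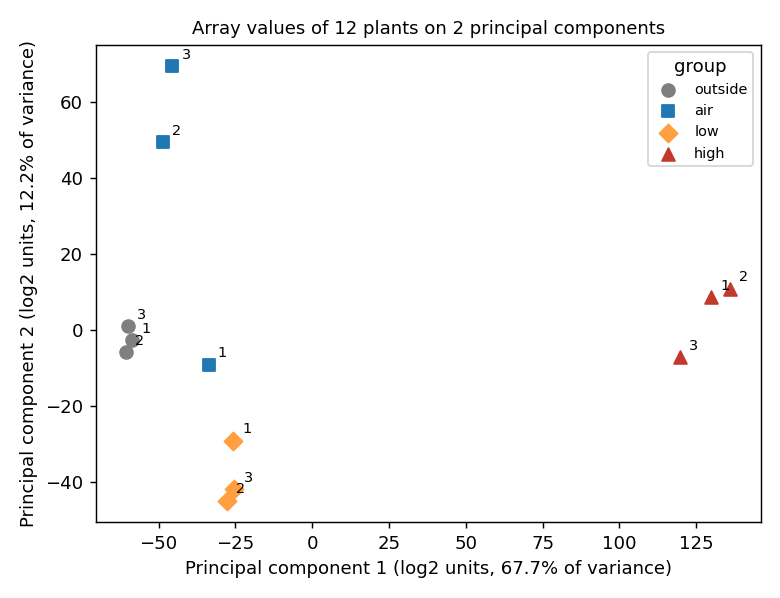
Each point is a plant, numbered within its group, placed on the first (67.7% of variance) and second (12.2%) principal components of the log2 values of all tested probe sets. The high plants lie at 119.7 to 136.1 on the first axis, and air plants 2 and 3 lie at 49.6 and 69.5 on the second.

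High against air asks what strong formaldehyde exposure did to leaf transcripts with the chamber held the same. The largest rises among the named genes were in small heat shock proteins, chaperones that bind unfolding proteins. AT5G51440 reached a log2 value of 13.63 ± 0.05 (SD, n = 3) in the high plants from 2.27 ± 0.19 in air, at least 2633-fold higher (adjusted p = 2.78e-08). AT1G53540 rose at least 1418-fold (log2 change 10.47) and AT2G29500 rose 834-fold (9.70). Hop3, a co-chaperone linking HSP70 and HSP90, rose by 8.19 on the log2 scale, and XTH18, a cell wall xyloglucan enzyme, rose by 8.91. In all, 7867 of 22746 probe sets were called, 3351 higher and 4516 lower, and 4298 of them changed at least 2-fold.

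Of the 28 heat shock genes listed, 6 were measured. All 6 rose, also 6 adjusted over the list alone, with a median log2 change of 8.55 (camera adjusted p = 2.39e-09). They included ROF2 (AT5G48570), a heat-induced immunophilin, at 7.40 ± 0.30 (SE). Genes for xenobiotic and carbonyl detoxification also rose, 7 of 7 measured (38 listed) and 7 adjusted over the list alone (median at least 5.36, camera adjusted p = 9.35e-09). Among them were the glutathione transferase GSTU25 (5.36, at least 41.0-fold), the glucosyltransferases UGT73B5 (7.09) and UGT73B4 (at least 67.7-fold) and the efflux carrier DTX3 (AT2G04050, at least 218-fold). The related glucosyltransferase UGT73C1, outside the list, rose at least 190-fold. High plant 3 stood lower than high plants 1 and 2 for DTX3 (8.57 against 10.79 and 10.32) and UGT73C1 (8.40 against 10.59 and 10.05). Of 5 measured reactive oxygen genes (24 listed), 3 rose, or 4 adjusted over the list alone (median 3.88, camera adjusted p = 2.64e-04). These were the zinc finger repressor STZ (6.20), the alternative NADH dehydrogenase NDB2 (3.88) and UPOX (AT2G21640, 6.35), while glutathione reductase GR had 0.30 (adjusted p = 0.0627). With an estimated correlation all 3 set calls held, at adjusted p = 0.00248, 0.0196 and 0.0196. The GAPDH 3' minus 5' signal moved along with these groups, at 0.23 ± 0.05 (SD, n = 3) in the high and 0.03 ± 0.10 in the air plants, as did the ubiquitin signal, at -0.48 ± 0.04 against -0.37 ± 0.06.

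The calmodulin-like genes CML38 (7.93, 244-fold) and CML37 (at least 37.4-fold) rose, 2 of 2 in the touch list and 2 adjusted over the list alone. The glutaredoxin GRX480 (6.88) and the transcription factor WRKY53 (2.22) rose, 2 of 2 in the salicylate list and 2 adjusted over the list alone. WRKY6 (3.89) rose as 1 of 3 senescence genes (1 adjusted over the list alone), and the cell wall peroxidase Prx37 rose at least 75.5-fold. In the endoplasmic reticulum list of 3 genes, the stress transcription factor BZIP60 rose by 3.65 and the calreticulin CRT1b fell by 1.35. ATERDJ3B, with a log2 change of -0.82 (adjusted p = 0.0503), passed only adjusted over the list alone, which gave 1 rise and 2 falls. The median of that list was -0.82 and its mean 0.50.

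Some genes of carbon fixation and of one-carbon metabolism fell, in lists too small for a set test. PRK, which makes the acceptor of carbon dioxide, fell by 0.96 (12.79 ± 0.03 against 13.75 ± 0.11, SD, n = 3; adjusted p = 1.29e-05) and SBPASE by 0.92, 2 of 3 Calvin-Benson genes and 2 adjusted over the list alone. RCA, the activator of Rubisco, had -0.14 (adjusted p = 0.37). In the one-carbon list, 2 of 4 fell and 2 adjusted over the list alone: GLDT (AT1G11860), of glycine cleavage, by 0.96, and the folate enzyme FOLD2 (AT3G12290) by 0.37. FDH, which oxidises formate, had -0.46 ± 0.27 (SE, adjusted p = 0.267), and FOLD1 (AT2G38660) had -0.31 (adjusted p = 0.128). The antenna genes LHCB4.1 and LHCB4.2 (0 of 2 called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05) had -0.01 and -0.06.

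The largest named falls against the air mean were AT3G28270 (-6.55), known only by its locus, and the sucrose transporter SWEET13 (-6.19, 73.2-fold; adjusted p = 2.65e-04), followed by TBL26 (-5.65), AT1G68600 (-5.51), AT3G15570 (-5.16), the lectin JAL23 (-5.02) and CRR42 (-4.92), an assembly factor of chloroplast NADH dehydrogenase. The size of several rests on air plants 2 and 3: SWEET13 read 10.57 and 9.80 there and 6.91 in air plant 1, and TBL26 read 11.81 and 12.28 against 7.67. Without air plant 1 SWEET13 had -7.28 and TBL26 -7.11, and JAL23 had -3.67 without air plant 3. Against the outside plants AT3G15570 (-5.91) and P1R1 (-5.29) fell more than SWEET13 (-5.19), AT3G28270 (-4.68) and TBL26 (-3.42). Further falls were the zinc finger gene GIS (-4.50), the sucrose phosphate synthase ATSPS4F (-4.30), P1R1 (-4.07), the cytokinin response regulator RR16 (-3.99) and AGO7 (-3.94), which acts in small RNA pathways. The starch gene APL3 fell by 2.64, 1 of 1 sugar-induced genes (1 adjusted over the list alone). Of 4 sugar starvation genes, IVD rose by 0.89 (1, and 1 adjusted over the list alone), with ETFQO at 0.29, MCCA at 0.36 and AKINBETA1 at 0.27.

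In the abscisic acid list, COR47 (1.25) and COR15B (1.07) rose, HIS1-3 fell by 3.74 and COR15A had 0.37, with the same 2 rises and 1 fall adjusted over the list alone. The size for HIS1-3 rests on air plants 2 and 3, at 10.02 and 11.19 against 7.48 in air plant 1. Of 4 flavonoid genes, DFR (at least 16.2-fold), UF3GT (at least 14.0-fold) and AT4G14090 (-3.43) fell, 3 of 4 and 3 adjusted over the list alone, with adjusted p from 0.0456 to 0.0487. Their air means rest on air plants 2 and 3, since DFR read 8.50 and 7.76 there and 2.11 in air plant 1. AT5MAT lay near the lowest value in both groups. The guard cell gene FMA fell by 0.83 (1 of 2, and 1 adjusted over the list alone), and the guard cell marker AT1G22690 had -0.58. Of sulfate assimilation, BGLU28 (at least 1.80, but 0.74 without high plant 3), SIR (-0.23) and APS3 (-0.05) gave 0 of 3 calls by limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. GI, of the clock, had 0.46 (0 of 1 called, 1 adjusted over the list alone). HRA1 (AT3G10040), of the low oxygen list, had -0.05 and the root marker PYK10 stood above the lowest value in air plant 3 alone (6.17) among the air and high plants, and 0 of 1 was called by limma in each list, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. SAG101 had 0.29.

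With each array left out in turn, 6077 of the probe sets (2698 higher, 3379 lower) were called in every fit of high against air. Of 68 named genes and list members, 7 lost a call in a fit: DFR, UF3GT and AT4G14090 (adjusted p up to 0.160 without air plant 2), FMA (up to 0.131 without high plant 2), IVD (up to 0.0766 without air plant 2), COR15B (0.0577 without air plant 2) and COR47 (0.0509 without high plant 2). Against the outside plants, COR15B was lower (-1.70, adjusted p = 0.00109), and APL3, HIS1-3, JAL23, COR47, DFR, UF3GT and AT4G14090 did not pass.

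**Figure D2:**
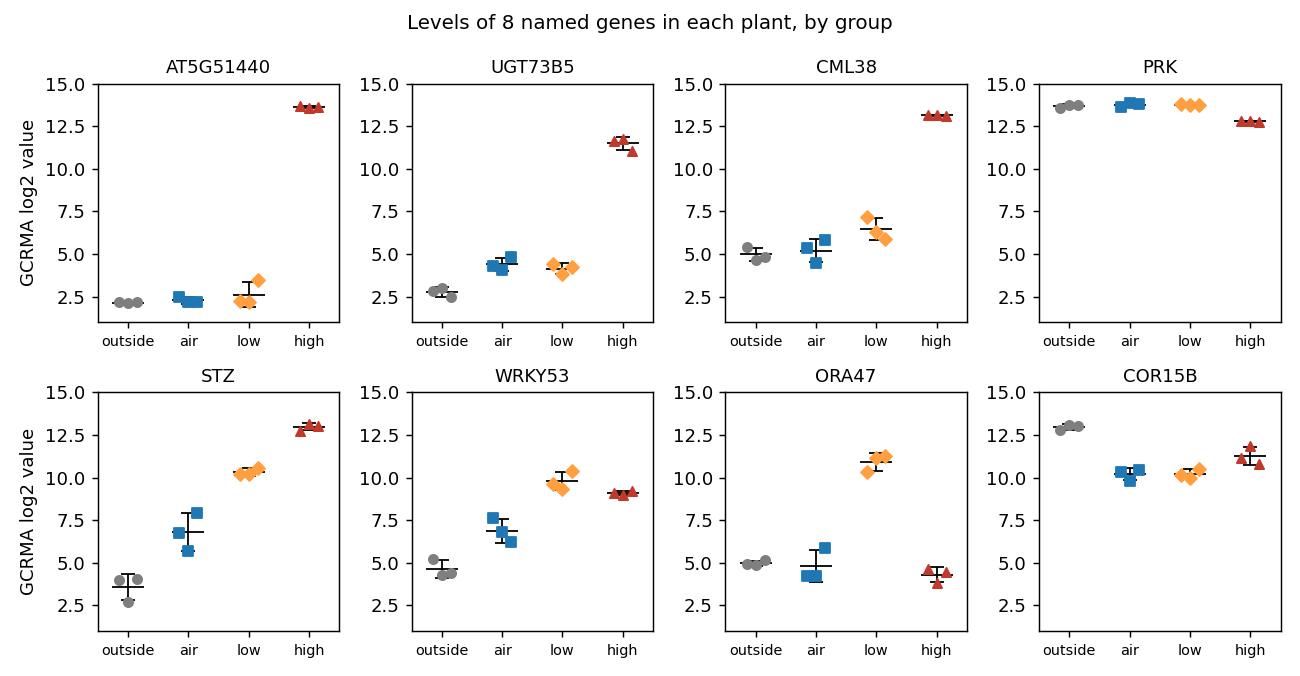
Log2 values (vertical axis, GCRMA units) of 8 named genes in the 12 plants by group, with the group mean and SD (n = 3) as bars. AT5G51440, UGT73B5 and CML38 stand above all other groups in the high plants, ORA47 stands apart in the low plants at 10.92, and COR15B is highest in the outside plants at 12.96.

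Low against air asks what 1 to 2 ppm formaldehyde did. ORA47, a transcription factor of jasmonate synthesis, rose 69.9-fold, to 10.92 ± 0.51 (SD, n = 3) from 4.79 ± 0.95 (adjusted p = 6.11e-04). The rises also included AT3G10930 (4.94), AT2G22880 (4.35, at least 20.5-fold), AT1G76600 (3.52), ZCF37 (3.02), AR781 (2.70) and PUB22 (2.88), a ubiquitin ligase of defence signalling. The glucosyltransferase UGT73B1 rose by 1.90. The transcription factors STZ (3.54), WRKY22 (3.46) and WRKY53 (2.90), and UGT76C2 (1.63), a cytokinin glucosyltransferase, rose too. The named falls were SWEET13 (-4.51), AT5G11930 (-3.15), AT1G80130 (-2.98), AT3G28540 (-2.88), GIS (-1.96), the jasmonate regulator MYC3 (-1.78) and the glucan dikinase PWD (-1.57).

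Heat shock and detoxification genes did not pass the test at this concentration. By limma, 0 of 6 heat shock genes and 0 of 7 detoxification genes were called, 0 of each adjusted over the list alone and 1 of each at an unadjusted p under 0.05. The heat shock genes AT1G53540 and HSP22.0 lay at or near the lowest value in the outside, air and low plants. So did the detoxification genes GSTU22, GSTU25, UGT73B4 and DTX3. A small rise from that level could have been missed. STZ was the single call among 5 reactive oxygen genes (1 adjusted over the list alone), and WRKY53 was that among 2 salicylate genes (1 adjusted over the list alone). The camera adjusted p was 0.673 for each of the 3 tested lists. In the reactive oxygen list the median was -0.17 and the mean 0.54. A fry set test that ignores direction passed for this list (adjusted p = 0.0102), but not for heat shock or detoxification (0.754 for each). Adjusted over the list alone, 3 of 4 flavonoid genes were lower than in air plants and 2 of 4 sugar starvation genes higher, with 0 of either called by limma over all probe sets (3 and 2 at an unadjusted p under 0.05). These values rest on air plants 2 and 3: DFR read 8.50 and 7.76 there and 2.11 in air plant 1, with the low plants at 2.11, and AKINBETA1 read 8.54 and 8.77 there and 10.20 in air plant 1, with the low plants at 10.67. In the endoplasmic reticulum list 3 of 3 genes passed adjusted over the list alone, 1 higher and 2 lower. The touch, clock, abscisic acid, sugar-induced and senescence lists had 1 such gene each. By limma over all probe sets, 0 were called in any of these lists. FDH had -0.02 ± 0.27 (SE).

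In total 283 of 22746 probe sets were called, 172 higher and 111 lower, with 180 of them changed at least 2-fold and 4065 at an unadjusted p under 0.05. With each array centred on its median the split was 488 higher and 190 lower. The count ran from 76 without low plant 2 to 2250 without air plant 1 (1111 higher, 1139 lower), and moved by more than 1.5 times in all fits but those without low plant 1 (297) and without high plant 3 (253). In every such fit 57 probe sets were called, 49 higher and 8 lower. ORA47, AT3G10930, AT2G22880, AT1G76600, ZCF37, PUB22, AR781 and UGT73B1 were among these. STZ (adjusted p = 0.101 without low plant 3), WRKY53 (0.0672 without air plant 2), WRKY22 (0.120 without low plant 3), UGT76C2 (0.118 without low plant 2) and all 7 named falls were not. SWEET13, for example, had 0.133 without air plant 3. With the 6 arrays of this comparison alone, all 19 named calls were lost. ORA47 then had a limma adjusted p of 0.103, PUB22 0.176, UGT73B1 0.169 and AR781 0.0629. The named calls thus rest on the spread estimated from all 12 arrays. Against the outside plants UGT76C2 had -0.38 (adjusted p = 0.502), and AT1G80130, AT5G11930, GIS, MYC3 and PWD did not pass.

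Both formaldehyde comparisons use the same air plants, so calls shared between them are not independent. Of the 172 probe sets higher in the low than in the air plants, 122 were also higher in the high plants, and of the 111 lower ones 72 were also lower. Independent calls would share 25.3 and 22.0, but that is not the value without a response, since the shared air plants add to it. Across probe sets the changes correlated at r = 0.378, where unchanged groups sharing the air plants gave 0.510 ± 0.231 (SD of the simulations). The covariance was 0.232, against 0.0296 ± 0.0196 (SD) simulated. With separate controls r was 0.342 (low against outside, high against air) and 0.177 (low against air, high against outside), against -0.015 ± 0.348 (SD) simulated. The covariances were then 0.222 and 0.118, against -9.63e-04 ± 0.0174 (SD) simulated. Measured against unchanged groups, r therefore stayed within about the spread of the simulations and the covariance lay above it, with shared and with separate controls. The simulated groups lacked the large high response, which alone can widen the range of the covariance. Its excess therefore does not show a shared response. The large high response also lowers the r that shared air plants alone would give, so 0.510 is too high a level to set against 0.378. The comparison of r therefore does not speak against a shared response either.

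High against low asks how the concentrations differed. Among the named genes the heat shock genes rose most, with AT5G51440 at 13.63 ± 0.05 against 2.62 ± 0.72 (SD, n = 3), a log2 change of 11.02 (adjusted p = 3.61e-08), AT2G29500 at 10.08 and AT1G53540 at least 1418-fold higher. XTH18 (8.95), Hop3 (at least 314-fold) and UGT73C1 (at least 190-fold) rose too. ORA47 fell by 6.61, and AT3G15570 (-5.90), AT1G07050 (-5.71), AT3G23880 (-5.31), RR16 (-5.20) and CRR42 (-4.90) fell.

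Of the fixed lists, heat shock rose in 6 of 6 (6 adjusted over the list alone; camera adjusted p = 1.60e-09), detoxification in 7 of 7 (7 adjusted over the list alone; 9.11e-09) and reactive oxygen in 4 of 5 (4 adjusted over the list alone; 8.67e-04). With an estimated correlation these had adjusted p = 0.00232, 0.0203 and 0.0291. STZ was 2.66 higher in the high plants, GRX480 7.05, CML38 6.68 and WRKY6 2.64. PRK fell by 0.98, SBPASE by 0.88 and GLDT (AT1G11860) by 1.18. Both guard cell genes fell, AT1G22690 by 1.57 and FMA by 1.27. Alongside these groups, the ubiquitin 3' minus 5' signal was lower, with -0.48 ± 0.04 (SD, n = 3) in the high and -0.30 ± 0.04 in the low plants, and the GAPDH signal was higher, with 0.23 ± 0.05 against -0.073 ± 0.073. In total 7687 probe sets were called (3515 higher, 4172 lower; 4093 at least 2-fold), 5844 of them in every fit that left out an array. Of 40 named genes and list members, 9 lost a call in a fit, with adjusted p of up to 0.130 (MCCA, without high plant 1): MCCA, FOLD2 (AT3G12290), GR1, COR15B, COR47, APL3, IVD, AKINBETA1 and AT1G22690 (up to 0.0844 without high plant 2).

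Air against outside compares plants in the chamber without added formaldehyde with plants kept outside. Among the genes lower in the air plants were the expansins EXPA16 (-5.21) and EXPB1 (-4.58, 24.0-fold, adjusted p = 0.00117). COR15B, which protects chloroplast membranes, was lower too, at 10.20 ± 0.34 against 12.96 ± 0.15 (SD, n = 3, log2 change -2.77). EXPA16 read 3.52, 2.52 and 3.02 in the air plants, but 4.15, 7.16 and 8.04 in the low and 7.00, 6.87 and 8.32 in the high plants. Its fall was therefore not shared by all plants in a chamber. EXPB1 did stay low, at 3.14 to 3.85 in the low and 2.11 to 3.23 in the high plants. COR15A fell by 1.46. The transcription factor genes STZ (3.20), WRKY53 (2.22) and WRKY47 (2.06, adjusted p = 0.00195) rose. The methionine sulfoxide reductases went apart, MSRB5 up by 2.52 and MSRB6 down by 2.13.

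Further rises were AT4G19430 (3.92), AT3G23550 (3.55), AT1G05575 (3.54), the gibberellin receptor GID1B (2.59), CYP71B36 (2.54), XTH16 (2.45), SUFE2 (4.28-fold) and the vacuolar protease GAMMA-VPE (2.04). Further falls were AT5G48490 (-6.44), AT1G20070 (-4.95), AT3G62820 (-4.58), the thionin THI2.2 (-3.31), GPDHC1 (-2.66), SIS (-2.61), UGT76C2 (-2.01) and the sugar transporter SWEET2 (-1.94). The air plants differed widely for AT5G48490 (7.10, 4.02 and 3.07 in air plants 1, 2 and 3) and AT3G62820 (7.12, 5.64 and 3.18). From the lists, UGT73B5 (1.64), APS3 (1.18) and APL3 (1.98) rose, and ALDH7B4 (-0.80), GR (-0.86) and FMA (-1.23) fell. The heat shock list had 0 of 6 called by limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, and the camera adjusted p was 0.900 for it, 0.841 for detoxification and 0.804 for reactive oxygen. The last had a median of -0.42, a mean of 0.41 and a downward camera test. Ignoring direction, the fry set test passed for reactive oxygen (adjusted p = 4.58e-04) and detoxification (0.0204), but not for heat shock (0.791). FDH had 0.01 ± 0.27 (SE).

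There were 1274 calls (705 higher, 569 lower; 583 at least 2-fold), and 424 were made in every fit that left out an array (235 higher, 189 lower). With each array centred on its median the majority turned, with 732 higher and 804 lower. The count was 603 without air plant 2, 631 without outside plant 3, 754 without air plant 3, 790 and 794 without outside plants 1 and 2, and 2137 without air plant 1. Of 32 named genes and list members, 17 lost a call in a fit, with adjusted p of up to 0.138 (APS3, without air plant 2): EXPA16 (0.0533 without air plant 2), WRKY53 (0.0644 without outside plant 3), COR15A, FMA, APS3, APL3, ALDH7B4, AT4G19430, GID1B, CYP71B36, XTH16, SUFE2, AT5G48490, AT3G62820, THI2.2, GPDHC1 and SWEET2. EXPB1, COR15B, STZ, WRKY47, MSRB5, MSRB6, GAMMA-VPE, SIS, UGT76C2, UGT73B5 and GR lost none. With the 6 arrays of this comparison alone, 23 of the 32 lost their call. Among them were STZ (limma adjusted p = 0.147), GAMMA-VPE (0.115), UGT76C2 (0.105), UGT73B5 (0.0836), MSRB5 (0.0724), GR (0.0712) and MSRB6 (0.0650). EXPB1, COR15B, WRKY47 and SIS kept theirs.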

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

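The tests on the air plants were chosen only after the result was seen. The tests on splits and on the chamber were planned.

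Some probe sets went opposite ways at the 2 concentrations. Against air, 16 rose in the low and fell in the high plants and 12 fell in the low and rose in the high plants, fewer than the 34.1 and 16.4 that independent calls would give, although the shared air plants make the calls dependent. High against low was also past the threshold for each, but choosing opposite calls all but fixes that outcome. Among the first, AT5G50450 had log2 changes of 1.36 (adjusted p = 0.0388) and -2.19. AT1G75960 had 2.18 (adjusted p = 0.0302) and -1.65, with the outside plants at 7.40, near the low plants at 7.87 and above air at 5.69. Among the others, MEF8S, an RNA editing factor, had -0.89 (adjusted p = 0.0108) and 1.06. AT2G31990 had -1.40 (adjusted p = 0.0412) and 1.45, but its outside plants (3.26) were level with the low plants (3.26) and air stood at 4.66, so that its fall exists only against air. These genes were chosen after their values were seen.

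On 191 probe sets air plants 2 and 3 lay within 2-fold of each other and their mean differed from air plant 1 by at least 4-fold, 84 higher and 107 lower. DFR and UF3GT, of anthocyanin synthesis, sat at the lowest value in air plant 1 and at 8.50 and 7.76 (DFR) in the other 2, and the auxin-conjugating GH3.3 read 9.37 in air plant 1 and 3.94 in both others; these genes were chosen after their values were seen. A mislabelled low plant is argued against: on 62 probe sets that part the low plants from air plants 2 and 3, air plant 1 sat at a median of 0.497 of the way, below each low plant left out of the choice (0.475 against 0.904, 0.492 against 1.01 and 0.546 against 1.03). RNA quality stays open: air plant 1 lay outside the range of the other arrays in 0 of 3 measures of 3' minus 5' signal, but air plants 2 and 3 had the lowest actin signals of the 12 arrays (0.61 and 0.54). A biological difference between plants that shared a chamber was not tested.

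A set of 83 probe sets was higher in the low plants than in both the high and the outside plants. The high plants were also in a chamber, so chamber placement alone does not give a difference between low and high. Low and high were separate chamber runs, however, so a difference between runs could give it. Chamber placement bears only on the height over the outside plants, to which it may contribute. The air plants, not used in the choice, sat at a median of 0.513 of the way from the outside to the low level. Air plant 1 was at 0.744, air plant 2 at 0.386 and air plant 3 at 0.321. For the height over the outside plants, chamber, run and formaldehyde therefore cannot be told apart in the set as a whole. Of the 83, 14 were also called higher in low than in air, 7 of them in every fit that left out an array. ORA47 is a member for which its own values argue against chamber placement alone, with air plants at 4.24, 4.24 and 5.89, outside plants at a mean of 4.98 and low plants at 10.92. They do not bear on a difference between chamber runs.

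The 6 plants of a comparison form 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the most calls in each comparison, with 7867 against at most 1 in the others (high against air), 283 against 3 (low against air), 7687 against 1 (high against low) and 1274 against 2 (air against outside). The other splits mix plants of both groups, so that a real difference enters their spread and lowers their calls. Their counts are therefore not a level for unchanged groups, and no conclusion is drawn from the contrast.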

How the results depend on the processing

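The settings with only air plant 1 in the air group and without probe sets near the lowest value were chosen only after the result was seen. High against air and high against low stayed within 1.5 times their counts in every setting run except the 2-fold minimum (4298 and 4093). With each array left out they ran from 6633 to 7850 and from 6390 to 7882, and with the replicate number as a block, although the numbers do not pair the plants (mean r -0.026), they were 7530 and 7276. Low against air moved most: 1196 in the upper 60% of probe sets, 678 with median centring, 7 with the 6 arrays alone, 1719 with array weights (836 higher, 883 lower), 81 with the block, 51 at an adjusted p under 0.01, 180 with the 2-fold minimum, 1775 with the outside plants as control, 500 with both control groups pooled, 160 with only air plant 1 (assumed to vary like the other plants; 43 higher and 117 lower, so the majority turned, with 48 calls shared with the 283), 1049 without probe sets near the lowest value and 76 to 2250 with each array left out. Air against outside gave 58 with the 6 arrays alone (26 higher, 32 lower), 845 with the block, 282 at 0.01, 583 with the 2-fold minimum, 586 with only air plant 1 and 603 to 2137 with each array left out. The calls of 3, 0, 3 and 0 gene lists, by set tests with a direction, were the same in every setting run, the block included. The 25th-percentile floor equals the lowest value, so that setting tests nothing. Fewer arrays or tested probe sets, or a stricter threshold, account by construction for part of these moves; for the others the cause was not tested.

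These results turned direction, and the cause was not tested. In high against air: with quantile normalization LHCB4.1 (0.085) and LHCB4.2 (0.049); with median centring LHCB4.1 (0.065), LHCB4.2 (0.017), APS3 (0.023) and AT3G10040 (0.024); with the outside plants GR (-0.56), SIR (0.24), APS3 (1.14), COR15B (-1.70), COR15A (-1.09), GI (-0.041), AKINBETA1 (-0.20) and AT1G22690 (0.89); with pooled controls GR (-0.13), SIR (0.0026), APS3 (0.54), COR15B (-0.32), COR15A (-0.36) and AT1G22690 (0.16); with only air plant 1 SIR (0.11), APS3 (0.57), ETFQO (-0.012), MCCA (-0.19), AKINBETA1 (-0.76) and SAG101 (-0.0076). FDH turned in low against air with median centring (0.048) and array weights (0.055), and in air against outside with the same (-0.0084 and -0.11). In low against air UGT76C2 was -0.38 against the outside plants. The camera list tests for low against air, past no threshold, turned for detoxification with median centring (camera adjusted p = 0.958) and for reactive oxygen against the outside plants (0.532). With each array left out, FDH ran from -0.34 to 0.16 (low against air) and -0.16 to 0.34 (air against outside), LHCB4.1 from -0.041 to 0.025, LHCB4.2 from -0.21 to 0.026, APS3 from -0.36 to 0.17 and AKINBETA1 from -0.045 to 0.79 (high against air). The lowest signal, shared by over 26.6% of probe sets per array, limits what a fall can show.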

Other observations

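The gene families were chosen only after the data were seen, while the tests on organelle transcripts were planned, apart from the version with array medians.

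Genes sharing a symbol stem were tested with camera. Together with the plastid and the mitochondrial set they made 21 sets, over which the p-values were adjusted. No set call named here held with an estimated correlation. Among serine carboxypeptidase-like genes (SCPL) 11 of 14 fell in the high against the air plants, with a median log2 change of -1.20 (camera adjusted p = 1.99e-04, and adjusted p = 0.240 with an estimated correlation), such as scpl50 (-2.52) and scpl35 (-2.19). Of 15 genes with the cytochrome P450 stem, which the cyclophilins CYP71 and CYP59 share, 12 fell and 1 rose (median -1.09, camera adjusted p = 0.00260, and adjusted p = 0.240 with an estimated correlation), among them CYP71B28 (-2.71). IQD genes, which bind calmodulin, fell in 7 of 11, as IQD24 did (-3.04), and rose in 1, IQD23 (1.58). Their median was -0.87 (camera adjusted p = 0.0190, and adjusted p = 0.314 with an estimated correlation). PRA1 genes of vesicle traffic rose in 6 of 10 (median 0.68, camera adjusted p = 0.00260, and adjusted p = 0.240 with an estimated correlation), with PRA1.B4 at 3.42. In low against air the P450 stem had a median of -0.51 (camera adjusted p = 0.00280, and adjusted p = 0.394 with an estimated correlation), with 0 of 15 genes called by limma and 8 at an unadjusted p under 0.05.

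Among 18 probe sets of mitochondrial transcripts, 9 rose and 0 fell by limma in high against low (median log2 change 1.14, camera adjusted p = 0.0108), and the set call was lost with an estimated correlation (adjusted p = 0.379). Against air 6 rose and 1 fell (median 0.58, camera adjusted p = 0.0574, and adjusted p = 0.548 with an estimated correlation), with 0.56 and 1.16 in high plants 1 and 2 and 0.11 in high plant 3. The 69 plastid probe sets had a median of -0.08 against air (1 rose, 1 fell; camera adjusted p = 0.913), with 0.13 and 0.18 in high plants 1 and 2 and -0.53 in high plant 3. The plastid medians per array, however, were 11.91, 11.91 and 11.01 in the high plants, each below those of the air plants (12.11, 12.18 and 11.98), so that the sign for high plants 1 and 2 depends on the measure.

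A smaller nuclear share of the labelled RNA could raise both kinds of organelle transcript alike in the high plants, and it stays open: the plastid median lay below the mitochondrial one by -0.66 ± 0.335 (SE), or -1.97 SE, short of the planned 2, while the medians taken per array differed by -5.16 SE. RNA quality may also enter: within groups the plastid median and the actin 3' minus 5' signal had r = -0.606 over 12 arrays (permutation p = 0.0367, adjusted 0.0404 over 2 relations; rho = -0.636, permutation p = 0.0297, adjusted 0.0593), and r = -0.502 without high plant 3 and air plant 1. For the mitochondrial median r was -0.590 (permutation p = 0.0404, with rho = -0.483 and permutation p = 0.116), and -0.264 without those plants, on which it rests. The permutation p-values of r and rho are too small to be used. All 12 deviations were exchanged freely, although they sum to 0 within each group. The actin signal was 0.89 in the high and 0.65 in the air plants, so that an inverse relation would lower the mitochondrial median in the high plants. The exact permutation test of actin over all 4 groups did not pass (p = 0.156), and high against air alone was not tested. The GAPDH and ubiquitin signals, which differed between the groups, were not set against the organelle medians. RNA quality therefore stays open. The planned bound for excluding it, an r under 0.3, was wrong because it set no limit below 0, where a strong inverse relation is also a relation.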
